A study of Homo sapiens with 9 samples.

How the data were processed

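RNA was measured by sequencing in 9 libraries of UMUC3, a human bladder cancer cell line, in 3 groups of 3 libraries. Per the labels, the NC libraries came from wild-type cells with no treatment, and the KO21 and KO2 libraries came from cells in which STIL had been knocked out with CRISPR-Cas9 and a guide against STIL. The labels did not say what sets KO21 apart from KO2. They also did not say whether the libraries of a group came from separate cultures. The edgeR and permutation p-values therefore measure only the spread between these libraries. Camera p-values compare a list with other genes, and p-values of chromosome arms come from random draws of genes, not from the spread between libraries. RNA was extracted with Trizol and sequenced on a BGISEQ instrument, per the labels.

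The submitters' processing notes named HISAT, Bowtie2 and the genome build GRCh38.p13. Versions, the role of each tool and the tool that counted reads were not given in the sources used here. The deposited table held 16886 genes, all protein-coding, with expected counts per gene and library that the authors had not normalised. Deposited FPKM values were scaled by the authors per kilobase and by sequencing depth, and deposited TPM values were scaled by the authors so that every library has the same total. The table also held the authors' group means, in which the group KO pools KO2 and KO21, and the authors' log2 fold changes of each knockout group over NC. The authors' p-values and q-values were headed DESeq2, per the file headers. Of the per-sample columns, 0 were left out of the account of units. The deposited fold changes and q-values were read only for the genes and counts given beside the new values.

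Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups, which left 12107 of 16886 genes, and libraries were scaled by trimmed mean of M-values (TMM). A robust quasi-likelihood model with 1 mean per group was fitted to all 9 libraries. The comparisons were the average of both knockout groups against NC, KO21 against NC, KO2 against NC, and KO21 against KO2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison, with no minimum fold. Levels are CPM (counts per 1e6 counts) after TMM scaling, and errors of log2 fold changes are standard errors from the edgeR fit. The level of STIL was also compared by an exact two-sided permutation test, 6 knockout libraries against 3 NC libraries. For 3 libraries against 3, the smallest p of such a test is 0.1, so single comparisons rest on the model across genes.

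Gene lists, 30 in number, were fixed before the data were examined, and the 27 lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values. Camera compares a list with all other genes; it was run with a preset correlation between genes of 0.01, with the correlation estimated from the data, and beside fry, which asks whether the genes of a list move on balance 1 way. Adjustment was over the 27 lists within a comparison, and the number of members called was also counted with p-values adjusted over the list alone. Pathways of the deposited KEGG annotation with 10 to 300 tested genes were tested in the same way, a choice made after the data were examined.

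The genes named in the text follow a rule fixed before the data were examined. It took STIL and a short list of single genes of interest. For both knockout groups against NC it took the 10 highest and 10 lowest log2 fold changes among genes called with 1 sign in the average and in each group, with all knockout libraries on 1 side of all NC libraries. For each other comparison it took the 6 highest and 6 lowest among called genes whose libraries did not overlap. Up to 3 members of each list per direction were added, those with the smallest p. A mean of at least 5 CPM over all libraries was required except for single genes and list members, and genes without a symbol or with a LOC symbol were skipped. Members of small counts, IGFBP2, COL3A1 and the HLA genes were named after their values were seen. Some genes that this rule took and 1 tested list are not reported here.

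Library totals of the expected counts ranged from 18902500 to 19756300. Intervals of ratios with 1 to 3 counts in a group are 95% intervals, and folds against a group with 0 counts were computed against a floor of 3 counts over the group; both cover counting error only. In data simulated at these depths with 200 changed genes, the edgeR calls for both knockout groups against NC recovered 49.3% of 1.5-fold changes, 91.0% of 2-fold changes and 100% of 4-fold changes, and 8 unchanged genes were called. Recovery of 1.5-fold changes was 41.8% for KO21 and 26.9% for KO2. A simulated list shifted 1.5-fold had a camera adjusted p of 2.4e-46, and 0 of 20 random lists were called. Genes were drawn independently there, so this could not test the preset correlation between genes.

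Alternatives fixed before the data were examined were DESeq2 1.42.0, DESeq2 size factors in edgeR, library size without TMM, no filter on low counts, a stricter filter (at least 5 CPM in at least 3 libraries), limma-voom, a fit of only the groups compared, the replicate number as a block, a minimum of 2-fold, and each library left out in turn. For lists they were the estimated correlation, fry, the block, library size, the stricter filter and each library left out. Fold changes were then found to follow the GC content of transcripts, so a correction was added after the data were examined. It set per-library offsets from loess curves (span 0.3) on the GC content and length of GENCODE 29 transcripts, known for 16396 of 16886 genes, and kept 11944 genes. In simulated unchanged data with a GC trend of this kind, 1254 genes were called without the correction and 10 with it, and 66 of 66 genes with 4-fold changes were recovered. The same correction was run with the replicate block and with KO21 replicate 1 left out. Splits of the libraries into groups of the same sizes were fitted in the same way: all 10 for 3 against 3, and 100 for 9 libraries, the real grouping being 1 of each. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.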

Results

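The data were read counts of protein-coding genes in 9 libraries of UMUC3 bladder cancer cells, 3 from wild-type control cells (NC) and 3 from each of the STIL knockout groups KO21 and KO2. STIL encodes a centriole assembly protein. Total counts per library ranged from 18902500 to 19756300, and 12107 of 16886 genes passed the filter and were tested. The first and second principal components held 46.8% and 31.7% of the variance. Pearson correlations of log2 CPM across genes were 0.976 to 0.993 within groups and 0.948 to 0.972 between groups, where genes are not independent replicates. Fold changes of the knockout groups over NC followed the GC content of the transcripts, with a Spearman correlation across genes of 0.614 for the average of both groups, 0.543 for KO21 and 0.566 for KO2. Between KO21 and KO2 this correlation was -0.0966. Corrected values, from a correction for GC content and length chosen after the data were examined, are therefore given beside the gene groups. The scaling also mattered. Relative to TMM, DESeq2 moved the median log2 fold change of all genes by 0.11 in the average of both groups and by 0.13 in KO2. Its size factors in edgeR moved it by 0.11 and 0.14. Library size without TMM moved it by -0.26 in the average, -0.20 in KO21, -0.32 in KO2 and 0.12 between KO21 and KO2. The GC and length correction moved it by 0.13, 0.10 and 0.15 in the average, KO21 and KO2. The median itself was -0.12, -0.09, -0.13 and 0.06 in the average, KO21, KO2 and KO21 against KO2 under TMM. Changes are fitted values under TMM unless another setting is named, and amounts by which genes rose or fell are log2 fold changes.

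**Figure D1:**
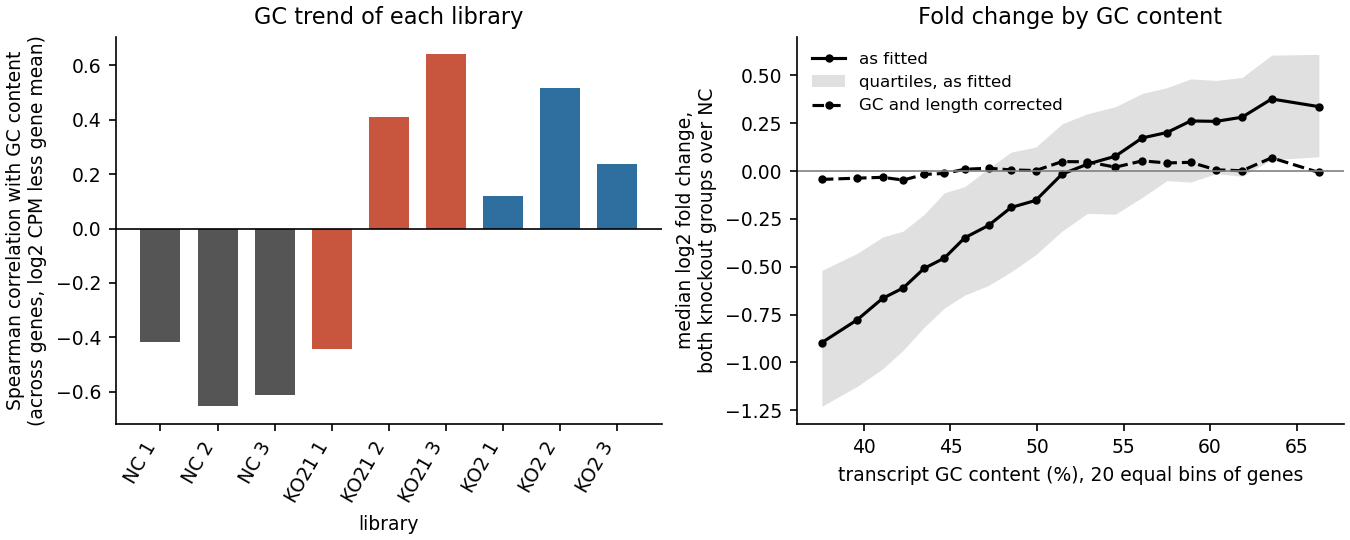
Left: Spearman correlation across genes between GC content and each library's log2 CPM less the gene mean (vertical axis, no unit), 1 bar per library, from -0.654 to -0.417 in NC and from -0.444 to 0.641 in the knockout libraries. Right: median log2 fold change of both knockout groups over NC (vertical axis) in 20 equal bins of genes by transcript GC content in percent (horizontal axis), as fitted with quartiles shaded and after the GC and length correction; the fitted medians climb with GC content and the corrected ones stay near 0.

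The labels named STIL as the edited gene, so its RNA was examined first. STIL lies on the minus strand of chromosome 1 at 47250139 to 47314896 in band 1p33, and its transcript has a GC content of 42.1%. STIL measured 7.0 ± 1.55 CPM in NC (SD, n = 3), 4.04 ± 2.25 CPM in KO21 (n = 3) and 3.09 ± 0.576 CPM in KO2 (n = 3). In KO21 the 3 libraries measured 6.62, 2.98 and 2.51 CPM, so replicate 1 lay within the NC range of 5.76 to 8.74 CPM. Over both groups STIL fell by 0.98 on the log2 scale (SE 0.27, edgeR adjusted p = 0.0095). The difference of -3.43 CPM between 6 knockout and 3 NC libraries had an exact two-sided permutation p of 0.0357, where the smallest possible was 0.0119. STIL fell in KO2, with a log2 fold change of -1.18 ± 0.32 (edgeR adjusted p = 0.0097). In KO21 its log2 fold change was -0.77 ± 0.32 (edgeR adjusted p = 0.072) and did not pass, and the difference between KO21 and KO2 was 0.40 ± 0.33 (edgeR adjusted p = 0.41). With the GC and length correction and all 9 libraries no comparison passed for STIL, at -0.32 ± 0.16 over both groups (edgeR adjusted p = 0.13), -0.23 in KO21 and -0.40 in KO2. In KO21 the call was present without replicate 1 (log2 fold change -1.34, edgeR adjusted p = 1.0e-04), with no filter on low counts, with limma-voom, with the replicate block, and with the correction when KO21 replicate 1 was left out (-0.49, adjusted p = 0.045), and in KO2 it ended without KO2 replicate 3 (-1.0, adjusted p = 0.070) and without NC replicate 3 (-0.99, adjusted p = 0.054). The authors' deposited log2 fold changes of STIL were -0.86 with both groups pooled as 1 (q = 0.0406), -0.71 in KO21 (q = 0.117) and -1.05 in KO2 (q = 3.6e-04).

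**Figure D2:**
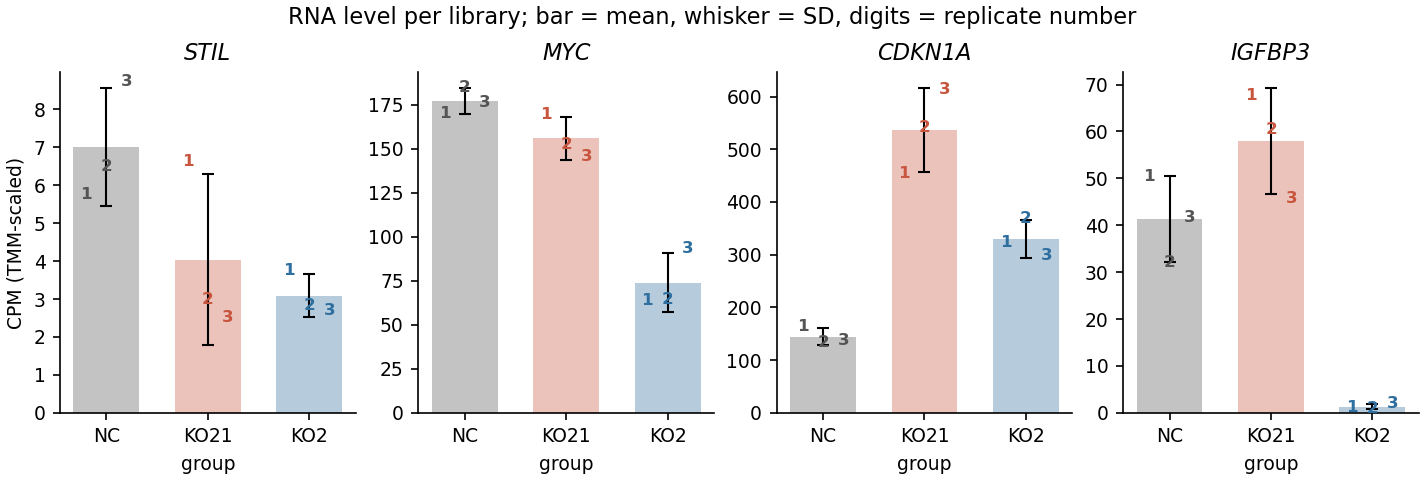
RNA level in CPM after TMM scaling (vertical axes, each from 0) of STIL, MYC, CDKN1A and IGFBP3 in NC, KO21 and KO2; bars are means of 3 libraries, whiskers are SDs and digits are replicate numbers at their values. CDKN1A is above NC in all 6 knockout libraries, MYC and IGFBP3 are lowest in KO2, and STIL of KO21 replicate 1 lies among the NC libraries.

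Both knockout groups against NC addressed what differs between cells labelled as STIL knockouts and wild-type cells, in a series whose title names mTOR signalling and c-myc. NC was untreated, so effects of the editing itself are not separated from those of STIL. Nor are differences of chromosome segments between the cell populations, which are taken up with the chromosome arms below. In the average of both groups CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 144 ± 16.6 CPM in NC (SD, n = 3) to 536 ± 79.3 CPM in KO21 and 330 ± 35.8 CPM in KO2, a log2 fold change of 1.54 ± 0.15 (edgeR adjusted p = 1.2e-06). FOS and FOSB, subunits of the AP-1 transcription factor, and EGR1, an early-response transcription factor, fell by 3.81, 2.97 and 3.01 on the log2 scale. FN1, which encodes fibronectin, fell from 68.5 ± 2.73 CPM to 10.2 ± 1.0 CPM in KO21 and 11.9 ± 1.87 CPM in KO2. MTOR, the kinase of both mTOR complexes, fell with a log2 fold change of -0.73 ± 0.15 (edgeR adjusted p = 0.0017), -0.46 after correction, and this fell short of 2-fold. MYC, a transcription factor of cell growth, fell in the average by 0.72 (SE 0.13, edgeR adjusted p = 8.6e-04) and was lower in KO2 than in KO21. The authors' deposited value for MYC, with KO21 and KO2 pooled as 1 group, was -0.52 and not called (q = 0.24). For IGFBP3, at 0.49 in KO21 and -4.95 in KO2, the authors' value for KO21 and KO2 pooled as 1 group was -0.39 (q = 0.93).

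Among the largest rises were those of SPOCD1, a germ-cell factor of DNA methylation, at 3.40 ± 0.19 on the log2 scale (edgeR adjusted p = 1.8e-09), AMPD3, an AMP deaminase, at 2.74, SECTM1, a secreted and transmembrane protein, at 2.68, and GNG11, a G protein gamma subunit, at 2.51. PLLP, a membrane protein of myelin, rose by 2.13, ALOXE3, an epidermal lipoxygenase, by 2.04, SLC22A18, a membrane transporter, by 1.94 and TM4SF19, a tetraspan membrane protein, by 1.87. CGB8, a chorionic gonadotropin subunit, and H2BC12, a histone H2B, rose by 1.99 and 1.86, and reads of either can be shared with close paralogues. Other large falls were those of KIRREL3, a cell adhesion molecule, at -3.25, PTK7, a receptor of Wnt signalling, at -3.18, HAPLN1, a link protein of the matrix, and MYH14, a non-muscle myosin, both at -2.53, and TGFBI, a secreted matrix protein, at -2.31. GPC4, a cell-surface proteoglycan, had -2.34, but with the 6 knockout libraries fitted as 1 group its log2 fold change was -1.57 and did not pass (edgeR adjusted p = 0.16).

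Genes of centriole duplication fell as a group: 0 rose and 14 fell of 30 tested, 15 with p-values adjusted over the list alone (camera adjusted p = 0.0022; adjusted p = 0.58 with an estimated correlation). CEP152, which recruits the kinase PLK4 to centrioles, fell by 2.70, PCM1, a scaffold of centriolar satellites, by 1.62 and CEP192, a scaffold of the pericentriolar material, by 1.47. After the GC and length correction 1 rose and 12 fell of 29 (camera adjusted p = 0.0084), with CEP152, PCM1 and CEP192 at -1.99, -0.91 and -0.80. With the stricter filter the centriole list did not pass (camera adjusted p = 0.50). Among G2/M and mitosis genes 1 rose and 20 fell of 35, 21 adjusted over the list alone (camera adjusted p = 3.7e-04; adjusted p = 0.58 with an estimated correlation). After correction 1 rose and 10 fell (camera adjusted p = 0.011). TTK, a spindle checkpoint kinase, fell by 1.87, TOP2A, a DNA topoisomerase, by 1.59 and ECT2, an activator of cytokinesis, by 1.5, or by 1.25, 0.95 and 0.81 after correction. AURKB, a mitotic kinase, was the gene that rose, by 0.53, a call that ended with both knockout groups fitted as 1 (edgeR adjusted p = 0.0503) and without NC replicate 3 (adjusted p = 0.092).

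Cholesterol synthesis genes and targets of SREBP, the sterol-sensing transcription factor, fell: 1 rose (TM7SF2, a sterol reductase) and 15 fell of 32, 16 adjusted over the list alone (camera adjusted p = 0.015; adjusted p = 0.44 with an estimated correlation). After correction 1 rose and 17 fell (camera adjusted p = 1.4e-04). HMGCS1, an enzyme of sterol synthesis, fell by 1.45 and SCD, a fatty acid desaturase, by 0.93, or by 0.71 and 0.48 after correction. The cholesterol list did not pass in KO2 alone, and its median log2 difference of KO21 less KO2 was -0.39. Of the targets of YAP and TEAD, transcription factors of the Hippo pathway, 0 rose and 15 fell of 23, 17 adjusted over the list alone (camera adjusted p = 1.4e-04; adjusted p = 0.58 with an estimated correlation). Corrected counts were 0 and 15 (camera adjusted p = 3.8e-06). CCN2 and CCN1, secreted matrix-associated proteins that are also on the matrix list, fell by 1.94 and 1.11. Of immediate early genes 4 rose (FOSL1, IER3, KLF2 and DUSP5) and 12 fell of 23, 16 adjusted over the list alone (camera adjusted p = 0.036; adjusted p = 0.58 with an estimated correlation). After correction 5 rose and 12 fell (camera adjusted p = 8.8e-04). FOSL1, another AP-1 subunit, rose by 1.07. The immediate early call ended with library size without TMM (camera adjusted p = 0.12) and without KO21 replicate 1 (0.12), KO2 replicate 1 (0.067), KO2 replicate 2 (0.052) or NC replicate 1 (0.16).

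Of cytosolic ribosomal protein genes 16 rose and 2 fell (RPL7 and RPS24) of 77, 9 adjusted over the list alone (camera adjusted p = 1.4e-04; adjusted p = 0.66 with an estimated correlation; fry adjusted p = 0.18). After correction 28 rose and 1 fell (camera adjusted p = 1.9e-04). RPL35 rose by 0.86 and RPL7 fell by 1.02, or by 0.61 after correction. The ribosomal list did not pass in KO21 alone, with 3 higher and 8 lower (camera adjusted p = 0.40, or 0.57 after correction). Among nuclear genes of oxidative phosphorylation 20 rose and 5 fell (UQCRB, UQCRC2, SDHD, ATP5PB and NDUFA5) of 68, 25 adjusted over the list alone (camera adjusted p = 4.0e-04; adjusted p = 0.58 with an estimated correlation; fry adjusted p = 0.12). After correction 31 rose and 2 fell (camera adjusted p = 5.6e-05). NDUFB10, a subunit of complex I, rose by 0.81 and COX6B1, a subunit of complex IV, by 0.72. The oxidative phosphorylation list did not pass in KO21 alone, with 10 higher and 8 lower (camera adjusted p = 0.20, or 0.057 after correction). Of 14 endothelial markers 6 were expressed highly enough to be tested, and of these 4 rose and 0 fell, 4 adjusted over the list alone (camera adjusted p = 0.0022; adjusted p = 0.58 with an estimated correlation). The corrected counts were equal (camera adjusted p = 0.0095). EGFL7, a secreted vascular factor, rose by 1.27, ROBO4, a guidance receptor, by 0.99 and ENG, a TGF-beta co-receptor, by 0.72, and the other was ESAM, an adhesion molecule.

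Of mTOR pathway components 11 rose and 9 fell of 44, 23 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.39; adjusted p = 0.58 with an estimated correlation). CASTOR1 and SESN2, amino acid sensors that restrain mTOR complex 1, rose by 1.58 and 0.79, and EIF4B, a translation initiation factor, fell by 0.67. USP28, a deubiquitinase, fell by 1.03, or by 0.68 after correction. MYC targets had 10 rising and 8 falling of 49, 18 adjusted over the list alone (camera adjusted p = 0.27). Nor did the lists that follow pass. Counts risen and fallen, the count adjusted over the list alone and the camera adjusted p were 0, 12, 12 and 0.30 of 34 for G1/S and DNA replication, 4, 15, 20 and 0.27 of 38 for amino acid and serine synthesis under ATF4, 2, 3, 4 and 0.46 of 24 for the unfolded protein response, and 10, 6, 17 and 0.16 of 34 for glycolysis and hypoxia. They were 2, 5, 8 and 0.50 of 16 for Hedgehog, 9, 7, 19 and 0.45 of 33 for interferon-stimulated genes, 8, 5, 14 and 0.41 of 25 for NF-kB and cytokines, and 6, 15, 23 and 0.16 of 34 for extracellular matrix. They were 3, 2, 6 and 0.56 of 11 for epithelial adhesion, 1, 2, 3 and 0.90 of 13 for luminal, 5, 3, 8 and 0.18 of 9 for basal urothelial genes, and 6, 8, 15 and 0.77 of 33 for apoptosis. For IGF signalling they were 2, 7, 10 and 0.17 of 14, for fibroblast markers 0, 2, 2 and 0.89 of 7, for keratinocyte markers 2, 2, 4 and 0.59 of 5, and for histones 5, 7, 12 and 0.53 of 26. Extracellular matrix passed after correction (7 rose and 14 fell, camera adjusted p = 0.016; adjusted p = 0.39 with an estimated correlation). Among the lists given here, median and mean differed in sign for the mTOR, unfolded protein, MYC target, interferon, epithelial, fibroblast and keratinocyte lists, and the test had the opposite sign to both for the luminal and apoptosis lists. Mitochondrially encoded genes (0 tested), haematopoietic markers (4) and neural and kidney markers (4) had too few members to test.

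In all, edgeR called 4843 of 12107 genes, 1863 higher and 2980 lower, of which 1519 changed at least 2-fold. The share of called genes that were higher was 38.5%, but 55.2% with DESeq2, 50.6% with its size factors in edgeR, 53.3% with the stricter filter, 19.6% with library size and 52.7% after the GC and length correction. That correction called 4456 genes, and 2874 of the 4802 calls with a corrected value kept call and sign while 3 were called with the opposite sign. The count was 2242 without NC replicate 3, 7271 without KO21 replicate 1, 3221 with the stricter filter and 2127 with the knockout libraries fitted as 1 group. The authors' deposited table, with KO21 and KO2 pooled as 1 group, listed 2668 genes at q under 0.05, 1604 higher and 1064 lower. The value nearest to it in kind is thus the 2127 of the fit with 1 knockout group.

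KO21 against NC addressed the same question in that group alone. FAM43A, a gene of little-known function, rose from 11.5 ± 1.39 CPM in NC to 131 ± 19.8 CPM in KO21 (SD, n = 3 each), a log2 fold change of 3.51 ± 0.18 (edgeR adjusted p = 5.7e-10). CCL5, a chemokine, rose by 3.33, FOXC2, a forkhead transcription factor, by 2.87, and KRTAP2-3, a keratin-associated protein with close paralogues, by 4.26. COL4A5 and COL4A6, chains of type IV collagen, were nearly absent: COL4A5 fell by 5.31, and COL4A6 had 1 count in KO21 against 258 in NC, a ratio of 226 (95% interval 40.2 to 8949). FGF12, a member of the fibroblast growth factor family, M1AP, a meiosis gene, and TP73, a transcription factor, fell by 5.24, 4.99 and 4.75. CDKN1A rose by 1.89 ± 0.16 (edgeR adjusted p = 3.0e-07). MYC measured 156 ± 12.3 CPM against 177 ± 7.34 CPM in NC and did not pass, at a log2 fold change of -0.18 ± 0.16 (edgeR adjusted p = 0.40) and -0.40 after correction; with the correction and without KO21 replicate 1 it was -0.59 and passed (edgeR adjusted p = 0.017). IGFBP3, which binds insulin-like growth factors, did not pass with edgeR at a log2 fold change of 0.49 ± 0.20 (adjusted p = 0.081), and it passed with DESeq2 (adjusted p = 0.036), with its size factors in edgeR (0.034), without KO21 replicate 3 (0.032) and without KO2 replicate 3 (0.0495). The authors' deposited value was 0.56 (q = 0.0397), and their value for MYC in KO21 was -0.10 (q = 0.77).

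Cholesterol synthesis genes fell in KO21: 1 rose (TM7SF2) and 19 fell of 32, 22 adjusted over the list alone (camera adjusted p = 1.1e-04; adjusted p = 0.051 with an estimated correlation). After correction 1 rose and 23 fell (camera adjusted p = 1.3e-07; adjusted p = 0.024 with an estimated correlation). HMGCS1 fell by 1.97, SCD by 1.04 and FDFT1, which makes squalene, by 0.81. MYC targets rose: 19 rose and 2 fell (NAP1L1 and DDX18) of 49, 25 adjusted over the list alone (camera adjusted p = 7.8e-04; adjusted p = 0.55 with an estimated correlation). After correction 24 rose and 2 fell (camera adjusted p = 0.0014). ODC1, the first enzyme of polyamine synthesis, rose by 1.38 and RRP9, a ribosomal RNA processing factor, by 0.98. NF-kB and cytokine genes rose, with 11 higher and 2 lower (BIRC3 and CXCL2) of 25, 13 adjusted over the list alone (camera adjusted p = 5.1e-04; adjusted p = 0.40 with an estimated correlation). Corrected counts were 13 and 2 (camera adjusted p = 0.0033). The cytokines IL11 and IL32 rose by 2.59 and 2.12. Centriole genes fell, with 0 higher and 12 lower of 30, 13 adjusted over the list alone (camera adjusted p = 0.0011; adjusted p = 0.55 with an estimated correlation). Corrected counts were 1 and 12 of 29 (camera adjusted p = 0.0048). With the stricter filter the list did not pass (0.43). G2/M genes had 1 higher (AURKB) and 14 lower of 35, 17 adjusted over the list alone (camera adjusted p = 0.0041; adjusted p = 0.60 with an estimated correlation), but did not pass after correction, with 5 higher and 13 lower (camera adjusted p = 0.11). YAP targets had 0 higher and 7 lower of 23, 7 adjusted over the list alone (camera adjusted p = 0.027; adjusted p = 0.60 with an estimated correlation). Corrected counts were 1 and 9 (camera adjusted p = 0.012). The fitted call ended without NC replicate 1 (0.068). Endothelial markers had 4 higher and 0 lower of 6, 4 adjusted over the list alone (camera adjusted p = 0.026; adjusted p = 0.60 with an estimated correlation), with the same counts but no pass after correction (camera adjusted p = 0.088) or without KO21 replicate 3 (0.052). Immediate early genes had 3 higher and 5 lower of 23, 11 adjusted over the list alone, without passing (camera adjusted p = 0.24), and passed after correction with 6 and 10 (camera adjusted p = 0.044; adjusted p = 0.69 with an estimated correlation). CCND1, which encodes cyclin D1, rose by 0.59, a call that ended with library size (edgeR adjusted p = 0.072) and without NC replicate 3 (0.057). COL6A1 and COL6A2, chains of type VI collagen, rose by 1.41 and 1.96, and mTOR components had 6 higher and 6 lower of 44, 15 adjusted over the list alone (camera adjusted p = 0.40).

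For KO21 edgeR called 3499 genes, 1602 higher and 1897 lower, 1493 of them at least 2-fold. After correction 4393 were called, 2414 higher and 1979 lower, and 2679 of 3457 calls kept call and sign with 0 reversed among the called. The count was 1727 without NC replicate 3, 6453 without KO21 replicate 1 and 2289 with the stricter filter, and the share that were higher was 45.8%, or 59.3% with DESeq2 and 57.9% with the stricter filter, while with library size 1054 of 3014 were higher. The authors' table listed 3230 genes at q under 0.05.

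KO2 against NC put the same question to the other knockout group. IGFBP3 fell from 41.4 ± 9.17 CPM in NC to 1.32 ± 0.574 CPM in KO2 (SD, n = 3 each), a log2 fold change of -4.95 ± 0.27 (edgeR adjusted p = 3.0e-09). MYC fell from 177 ± 7.34 to 73.9 ± 16.9 CPM, a log2 fold change of -1.26 ± 0.16 (edgeR adjusted p = 2.7e-05), -1.51 after correction. The authors' deposited values in KO2 were -4.84 for IGFBP3 (q = 9.0e-72) and -1.14 for MYC (q = 7.4e-13). CTSZ, a lysosomal protease, SLIT3, a secreted guidance factor, and LRRC15, a membrane protein, fell by 5.82, 4.74 and 4.15. MSC, which encodes the transcription factor musculin, had 0 counts in KO2 against 588 in NC, at least 156-fold lower with a floor of 3 counts over the group. COL4A6 and COL4A5 rose by 2.13 and 1.10, and TNC, a matrix protein, by 2.49. LYL1, a blood-lineage transcription factor, and LDLRAD2, a receptor-like protein, rose by 4.44 ± 1.15 (edgeR adjusted p = 0.022) and 3.32 ± 0.92 (0.027), with 22 ± 17 and 48.1 ± 32.8 CPM in KO2 (SD, n = 3). Both calls ended with the replicate block (edgeR adjusted p = 0.059 and 0.088), without KO2 replicate 2 (0.081 and 0.11) and without NC replicate 1 (0.082 and 0.086), NC replicate 2 (0.081 and 0.094) or NC replicate 3 (0.072 and 0.091), and that of LDLRAD2 also without KO21 replicate 2 (0.054).

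Ribosomal protein genes rose in KO2, with 36 higher and 3 lower (RPL7, RPL6 and RPS24) of 77, 42 adjusted over the list alone (camera adjusted p = 2.4e-08; adjusted p = 0.49 with an estimated correlation). Corrected counts were 44 and 3 (camera adjusted p = 5.2e-07). RPL35 and RPL12 rose by 1.2 and 0.88. Oxidative phosphorylation genes had 30 higher and 3 lower (UQCRB, ATP5PB and NDUFS1) of 68, 33 adjusted over the list alone (camera adjusted p = 9.7e-06; adjusted p = 0.49 with an estimated correlation). Corrected counts were 42 and 1 (camera adjusted p = 4.0e-06). YAP targets had 0 higher and 14 lower of 23, 15 adjusted over the list alone (camera adjusted p = 7.0e-05; adjusted p = 0.49 with an estimated correlation). Corrected counts were 1 and 15 (camera adjusted p = 1.0e-05). G2/M genes had 0 higher and 21 lower of 35, 25 adjusted over the list alone (camera adjusted p = 7.3e-04; adjusted p = 0.49 with an estimated correlation). Corrected counts were 1 and 11 (camera adjusted p = 0.013). Matrix genes fell, with 4 higher (TNC, ITGA5, MMP14 and TIMP1) and 16 lower of 34, 20 adjusted over the list alone (camera adjusted p = 0.026; adjusted p = 0.49 with an estimated correlation), the same counts after correction (camera adjusted p = 0.0021), and no pass with library size (0.087) or without KO2 replicate 1 (0.051). FN1 fell by 2.52, GPC4 by 3.96, and COL3A1, a chain of type III collagen, had 1 count against 542 in NC, a ratio of 431 (95% interval 77.1 to 17070), and 2 counts in KO21, a ratio of 237 (95% interval 65.3 to 1963). IGF signalling genes had 2 higher (IGFBP6 and IGFBP4) and 7 lower of 14, 11 adjusted over the list alone (camera adjusted p = 0.026; adjusted p = 0.49 with an estimated correlation), but did not pass after correction, with 2 and 5 (camera adjusted p = 0.145), or with library size (0.19). IGF2, a growth factor, fell by 1.80, IGFBP6 rose by 1.89, and IGFBP2, another binding protein, had 2 counts against 482 in NC, a ratio of 192 (95% interval 52.8 to 1588). Immediate early genes had 6 higher (FOSL1, JUND, IER3, KLF2, NR4A1 and DUSP5) and 13 lower of 23, 19 adjusted over the list alone (camera adjusted p = 0.016; adjusted p = 0.49 with an estimated correlation). The corrected counts were equal (camera adjusted p = 0.0012). The fitted call ended with library size (0.096) and without NC replicate 1 (0.056). Centriole genes had 0 higher and 12 lower of 30, 12 adjusted over the list alone (camera adjusted p = 0.028; adjusted p = 0.49 with an estimated correlation), but did not pass after correction, with 1 and 7 of 29 (camera adjusted p = 0.12), with the stricter filter (0.83) or without KO2 replicate 3 (0.11). Endothelial markers had 4 higher and 0 lower of 6, 5 adjusted over the list alone (camera adjusted p = 0.0020; adjusted p = 0.49 with an estimated correlation). The corrected counts were equal (camera adjusted p = 0.0070).

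MYC targets in KO2 had 2 higher and 15 lower of 49, 17 adjusted over the list alone, without passing (camera adjusted p = 0.35), but passed after correction with 4 higher and 17 lower (camera adjusted p = 0.0075; adjusted p = 0.45 with an estimated correlation). UTP20 and NOLC1, factors of ribosome assembly, fell by 2.36 and 0.91, or by 1.58 and 0.59 after correction. NF-kB and cytokine genes had 3 higher and 10 lower of 25, 13 adjusted over the list alone (camera adjusted p = 0.15), and passed after correction with the same counts (camera adjusted p = 0.024; adjusted p = 0.43 with an estimated correlation); the chemokines CXCL1, CCL2 and CCL5 fell by 2.57, 2.44 and 2.04. Genes of amino acid and serine synthesis under ATF4 had 2 higher and 15 lower of 38, 17 adjusted over the list alone, without passing (camera adjusted p = 0.059), and passed after correction with 2 and 17 (camera adjusted p = 0.0049; adjusted p = 0.41 with an estimated correlation). FOXC2 fell by 2.03, CDKN1A rose by 1.19 ± 0.16 (edgeR adjusted p = 4.4e-05), and mTOR components had 10 higher and 12 lower of 44, 23 adjusted over the list alone (camera adjusted p = 0.49).

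For KO2 edgeR called 4955 genes, 1923 higher and 3032 lower, 2158 of them at least 2-fold. After correction 4785 were called, 2556 higher and 2229 lower, and 3197 of 4910 calls kept call and sign with 1 called the opposite way. The count was 2926 without NC replicate 3, and the share that were higher was 38.8%, or 54.0% with DESeq2, 52.5% with the stricter filter and 19.4% with library size. The authors' table listed 5665 genes at q under 0.05.

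**Figure D3:**
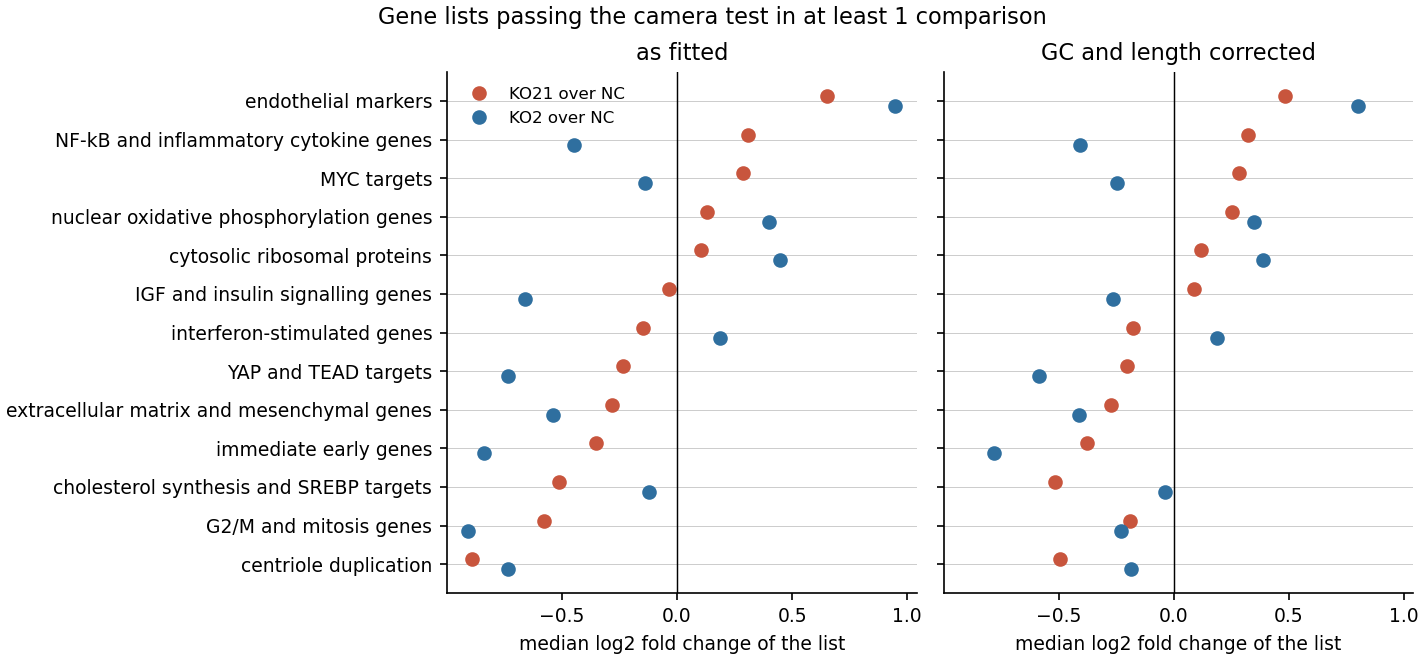
Median log2 fold change over NC (horizontal axes) of the gene lists that passed the camera test in at least 1 comparison (vertical axis), for KO21 and KO2, as fitted on the left and after the GC and length correction on the right. The medians of NF-kB genes and MYC targets lie on opposite sides of 0 in KO21 and KO2 in both panels, and those of the G2/M and centriole lists move towards 0 after correction.

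KO21 against KO2 asked whether the knockout groups differed from each other. MYC was higher in KO21 by 1.08 ± 0.16 on the log2 scale (edgeR adjusted p = 9.3e-05), and IGFBP3 by 5.43 ± 0.28 (edgeR adjusted p = 3.5e-10), at 58.0 ± 11.2 against 1.32 ± 0.574 CPM (SD, n = 3 each). CCL5, FOXC2 and CTSZ were higher in KO21 by 5.37, 4.90 and 5.96. M1AP, FGF12, COL4A5, TP73 and LRATD1, a lecithin retinol acyltransferase domain protein, were lower in KO21 by log2 differences of -7.20, -6.45, -6.41, -4.36 and -4.05. COL4A6 had 1 count in KO21 against 911 in KO2, a ratio of 1001.4 (95% interval 179 to 39595), and MSC, at 709 counts in KO21 and 0 in KO2, was at least 215-fold lower in KO2. CDKN1A was higher in KO21 by 0.70 ± 0.16 (edgeR adjusted p = 0.0035), CCND1 by 0.64 and CDKN1B, a cell cycle inhibitor, by 0.95.

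MYC targets were higher in KO21: 23 higher and 1 lower (CCND2) of 49, 29 adjusted over the list alone (camera adjusted p = 1.1e-06; adjusted p = 0.23 with an estimated correlation). Corrected counts were 32 and 1 (camera adjusted p = 2.7e-07). UTP20, ODC1 and NOLC1 were higher by 2.62, 1.64 and 1.14. NF-kB and cytokine genes had 11 higher and 1 lower (CSF3) of 25, 14 adjusted over the list alone (camera adjusted p = 6.1e-07; adjusted p = 0.12 with an estimated correlation). Corrected counts were 14 and 2 (camera adjusted p = 7.6e-06), with IL32 and CXCL1 higher by 3.29 and 3.16. IGF signalling genes had 7 higher and 1 lower (IGFBP6, at -1.96) of 14, 9 adjusted over the list alone (camera adjusted p = 0.0045; adjusted p = 0.25 with an estimated correlation). Corrected counts were 8 and 1 (camera adjusted p = 0.045), and did not pass with library size (0.055). Cholesterol genes were lower in KO21, with 2 higher (ACACA and ACLY) and 11 lower of 32, 16 adjusted over the list alone (camera adjusted p = 7.4e-04; adjusted p = 0.12 with an estimated correlation). Corrected counts were 3 and 19 (camera adjusted p = 6.7e-04). FADS2, a fatty acid desaturase, and FDFT1 had log2 differences of -1.40 and -1.10. Ribosomal protein genes had 2 higher (RPL6 and RPL8) and 20 lower of 77, 23 adjusted over the list alone (camera adjusted p = 6.1e-07; adjusted p = 0.58 with an estimated correlation; fry adjusted p = 0.058). Corrected counts were 2 and 30 (camera adjusted p = 6.6e-05). Oxidative phosphorylation genes had 2 higher (NDUFB9 and CYC1) and 18 lower of 68, 21 adjusted over the list alone (camera adjusted p = 7.4e-04; adjusted p = 0.58 with an estimated correlation; fry adjusted p = 0.082). Corrected counts were 3 and 25 (camera adjusted p = 0.013). RPS15A and NDUFA1, a complex I subunit, had log2 differences of -1.89 and -1.43. Interferon-stimulated genes had 2 higher (HERC6 among them) and 10 lower of 33, 16 adjusted over the list alone (camera adjusted p = 0.0091; adjusted p = 0.35 with an estimated correlation). Corrected counts were 3 and 14 (camera adjusted p = 0.015). Hedgehog genes went both ways, with 4 higher and 3 lower of 16, 7 adjusted over the list alone (camera adjusted p = 0.30): the transducer SMO and the transcription factor GLI2 were higher in KO21 by 3.55 and 2.93, and GLI3, another GLI factor, had a log2 difference of -1.90.

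Between KO21 and KO2 edgeR called 2952 genes, 1610 higher in KO21 and 1342 lower, 1199 of them at least 2-fold. With the stricter filter 1156 were higher and 1351 lower, and with library size 1884 and 1131. After correction 4798 were called, where 2878 of 2916 calls kept call and sign with 0 reversed among the called. In the same direction in both groups against the shared NC libraries 1744 genes changed, 710 higher and 1034 lower, and 182 changed in opposite directions. Independent lists of these sizes would share 730 genes in the same direction. In 10 simulated sets of unchanged groups with shared controls the count was 0. With no changed genes, the adjustment of p-values sets a count near 0 in advance. It therefore does not show how many of the 1744 genes owe their call to the shared controls. The correlation of fold changes was 0.489 observed. In the simulated sets, where the shared controls were its only source, it was 0.477. The simulated sets held no GC trend, so they do not show the count that a trend common to both groups would give. A correlation is scaled by the spread of the fold changes, and the simulated sets held no changed genes. The 0.477 is therefore not the part of the observed correlation that came from the shared controls. The covariance of the fold changes was 0.330 observed and 0.0363 in the simulated sets, an excess of 0.294. This excess may hold the GC trend. The same-direction count was 632 without NC replicate 3, 3985 without KO21 replicate 1 and 1042 with the stricter filter; after correction it was 1707, with 971 higher, 736 lower and 538 in opposite directions, where independent lists would share 886. The corrected fold changes had a covariance of 0.184 and a correlation of 0.350. The 0.477 of the simulated sets, which were not corrected and held no changed genes, is no reference for that correlation.

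**Figure D4:**
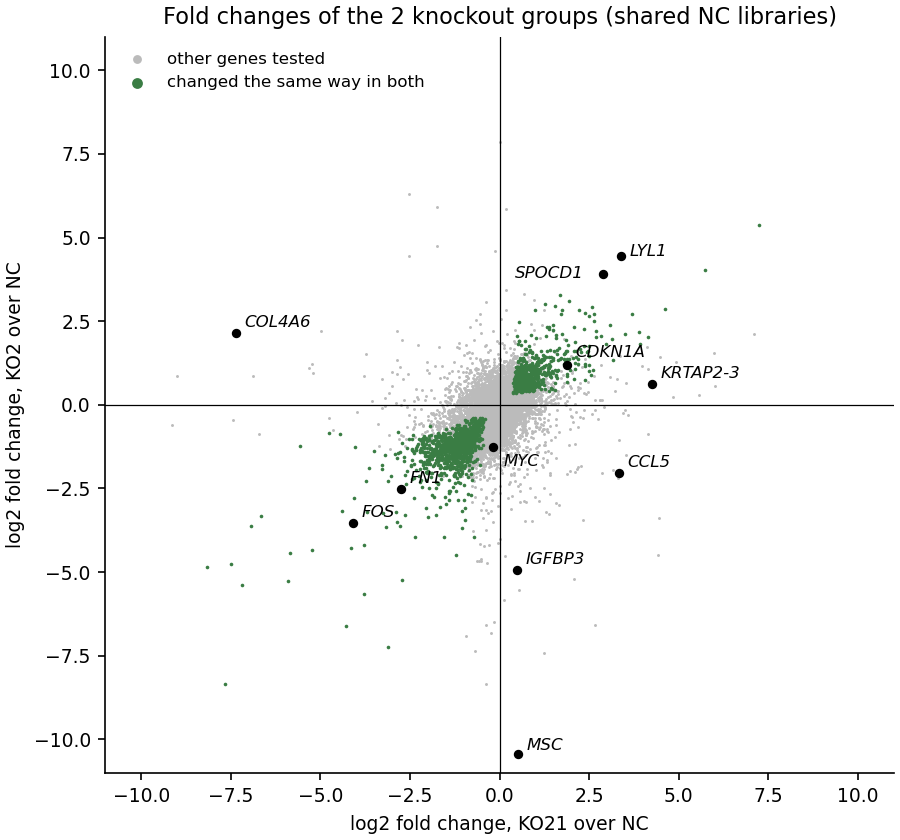
Log2 fold change over NC of each tested gene in KO21 (horizontal axis) and KO2 (vertical axis), with the 1744 genes changed the same way in both in green and named genes in black. CDKN1A and SPOCD1 lie high and FN1 and FOS low in both groups, while CCL5 and COL4A6 lie on opposite sides; the fitted values of COL4A6 in KO21 (1 count) and MSC in KO2 (0 counts) are no bounds.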

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

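The tests of the GC trend, of the corrected change of STIL, of the label of KO21 replicate 1, of chromosome segments and of the neighbours of MYC were chosen after the results were seen. The comparison of STIL with matched genes was written down before its result was seen, and the edgeR tests of the difference between KO21 and KO2 before the data were examined.

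A first pattern is the climb of fold changes over NC with GC content, at a Spearman correlation across genes of 0.614 for both groups. A difference in depth is argued against, since the highest total count was 1.05 times the lowest. Libraries of the same group also differed along GC: in each group at least 1 library's deviation from its group mean had a correlation with GC of 0.525 or more in size, as KO21 replicate 1 at -0.747 and replicate 3 at 0.718, which is consistent with GC-dependent recovery that differs between libraries. An effect of the knockout on GC-rich and GC-poor genes cannot be told apart from this, since the groups are confounded with it: the GC correlations of the 6 knockout libraries (median 0.323) and the 3 NC libraries (-0.654 to -0.417) differed at an exact permutation p of 0.0357, with KO21 replicate 1 at -0.444 within the NC range. The corrected lists and counts thus assume that the trend holds no biology, and the fitted ones that it is all biology.

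A second pattern is the lower STIL RNA. Of the 200 tested genes nearest to STIL in GC content, length and expression, 51 or 25.5% fell as much, and the median of all 200 was -0.75, so GC-dependent recovery may account for much of the fall. Loss of edited STIL transcripts stays open, as an edit need not change the RNA. The correction took STIL from -0.98 ± 0.27 to -0.32 ± 0.16 (edgeR adjusted p = 0.127), a call that ended because the fold shrank more than its error. With the correction and without KO21 replicate 1 it was -0.44 (edgeR adjusted p = 0.0175). That library had the highest STIL of the KO21 libraries, so leaving it out deepens the fall by selection. No other library was left out under the correction, so this value does not decide the question. STIL of KO21 replicate 1 lay at the NC level, and a mislabelled NC library is argued against, since 90 of the 100 genes that most separate the other KO21 libraries from NC lay nearer to KO21 in it. The rule asked for at least 90, so it was only just met, and it addresses only an exchange of the whole library. Why STIL lay at the NC level in that library was not tested.

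Another pattern is the difference between KO21 and KO2 in 2952 genes, with MYC lower in KO2. GC-dependent recovery is argued against, as 98.7% of these calls kept call and sign after the correction. Corrected differences of genes 20 tested genes apart on a chromosome correlated at 0.107 (highest of 1000 random gene orders, 0.0378), so copy number differences of chromosome segments between the cell populations may contribute; on 8q, which holds MYC, 81.2% of 266 genes were higher in KO21, at a median of 0.50. The 40 tested genes nearest to MYC, from 123002560 to 142545009 on chromosome 8, had a corrected median of -0.40 in KO2 over NC. A lower copy number of that segment may thus be part of the fall of MYC. MYC lay at -1.11 relative to that median (SE of MYC alone 0.188), and 0 of the 40 genes fell as much. These values argue against a lower copy number of that segment as the whole of the fall. A copy number change narrower than the segment was not tested. No DNA was measured, and a different response of KO21 and KO2 to the knockout stays open and untested.

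The remaining results differed between KO21 and KO2 in their change against the shared NC libraries, tested as KO21 less KO2 in edgeR with adjusted p from 1.2e-11 to 0.0461. In log2 units the difference was 5.43 for IGFBP3, 1.08 for MYC, 0.70 for CDKN1A, 0.64 for CCND1 and 0.95 for CDKN1B. Among matrix and adhesion genes it was -9.50 for COL4A6 (a fitted value with 1 count in KO21, no bound), -6.41 for COL4A5, 3.44 for COL6A1, 2.67 for COL6A2, -1.94 for TNC, 3.23 for GPC4, -1.48 for HAPLN1 and 0.66 for PTK7. For secreted and signalling proteins it was 5.37 for CCL5, 2.46 for CCL2, 3.16 for CXCL1, 1.57 for IL11, 3.29 for IL32, 1.25 for IGF2, -1.96 for IGFBP6, 4.4 for SLIT3, -6.45 for FGF12 and -1.17 for GNG11. For transcription factors and the Hedgehog pathway it was 4.90 for FOXC2, -4.36 for TP73, -1.45 for EGR1, 0.64 for FOSB, 2.93 for GLI2, -1.90 for GLI3 and 3.55 for SMO. For metabolic genes it was -1.40 for FADS2, -1.10 for FDFT1, -1.04 for HMGCS1, 0.70 for AMPD3, 0.85 for ALOXE3, 1.64 for ODC1 and 1.05 for CASTOR1. For ribosome and respiratory genes it was -1.89 for RPS15A, -0.92 for RPL12, -0.66 for RPL35, 2.62 for UTP20, 1.14 for NOLC1, 0.72 for RRP9, -1.43 for NDUFA1 and -0.63 for COX6B1. For the other named genes it was -1.12 for TTK, 5.96 for CTSZ, 3.68 for FAM43A, 3.64 for KRTAP2-3, 3.59 for LRRC15, 1.52 for MYH14, 1.85 for HLA-DRB1, 1.69 for HLA-DRB5, -7.20 for M1AP, -4.05 for LRATD1, -0.95 for H2BC12, -1.75 for PLLP, -0.90 for SLC22A18, -1.04 for SPOCD1 and -0.74 for TM4SF19.

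Camera passed the difference for 7 lists, with median log2 differences of 0.81 for IGF signalling genes, unchanged with IGFBP2 at its interval's lower end, 0.67 for NF-kB and cytokine genes, 0.48 for MYC targets, -0.23 for oxidative phosphorylation, -0.28 for interferon-stimulated genes, -0.34 for ribosomal proteins and -0.39 for cholesterol synthesis; 0 of these passed with an estimated correlation, where 4 of 27 lists had an unadjusted p under 0.05, while fry passed 14 lists.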

How the results depend on the processing

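The GC and length correction was chosen after the data were examined and the other alternatives before. Among counts of genes and lists and the STIL level, 73 values under the other settings lay within 1.5 times the count, or kept direction and call, 20 counts moved further and 2 STIL values lost their call. The stricter filter gave 3221 genes for both knockout groups, 2289 for KO21 and 1042 in the same direction. A minimum of 2-fold gave 1519 genes for both groups, 1493 for KO21, 2158 for KO2, 1199 between KO21 and KO2, and 705 in the same direction. Fitting the 6 knockout libraries as 1 group, which adds the difference between KO21 and KO2 to the spread, gave 2127. Between KO21 and KO2 the correction gave 4798 genes, 4557 with the replicate block and 4638 with KO21 replicate 1 left out; the correction lowered the common dispersion from 0.0300 to 0.0120. STIL over both groups was -0.32 with the correction (edgeR adjusted p = 0.127) and -0.34 with correction and block (0.120), and the cause was not tested beyond the matched genes.

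With the replicate number as a block edgeR called 4483 genes for both groups, 3212 for KO21, 4564 for KO2, 2565 between them and 1619 in the same direction, with STIL at -1.05 (adjusted p = 0.00504) and 8, 7, 9 and 7 lists passing. The numbers do not appear to pair the libraries: 2 of 9 same-number pairs had correlations of their deviations above 0.1, over a range of -0.440 to 0.419.

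For lists, camera with an estimated correlation passed 0 in each of the 4 comparisons (1, 2, 0 and 4 of 27 at an unadjusted p under 0.05, for both groups, KO21, KO2 and KO21 against KO2). After the GC and length correction the estimated correlation left 1 list passing, cholesterol synthesis in KO21 (camera adjusted p = 0.024). Fry, which does not compare a list with other genes, passed 14, 14, 18 and 14.

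Leaving out 1 library at a time gave 2242 (without NC replicate 3) to 7271 (without KO21 replicate 1) genes for both groups, 1727 to 6453 for KO21 and 2926 to 6519 for KO2 (without the same libraries), 2185 (without KO21 replicate 2) to 3576 (without KO21 replicate 1) between KO21 and KO2, and 632 to 3985 in the same direction, again without NC replicate 3 and KO21 replicate 1. STIL ranged from -1.26 (without KO21 replicate 1) to -0.787 (without NC replicate 3, where its call ended). Lists passing ranged from 7 to 8, 6 to 9, 8 to 11 and 7 to 8.

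Of single named genes and of lists that passed, under other settings, 1586 values kept direction and call, 75 lost the call, 7 gained it and 0 reversed; with 1 library left out 1370 kept it, 22 lost it and 3 gained it. Lists that had not passed are not in this tally. At these depths simulated 1.5-fold changes were recovered in 26.9% to 49.3% of genes. That simulation held far fewer changed genes than were called in the data, and the adjusted p depends on how many genes change. It therefore cannot tell how small a change was detectable in the data. There, 4843 genes were called for both groups, 1519 of them at least 2-fold.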

Other observations

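Outside the lists fixed beforehand, some HLA genes rose over both knockout groups; these genes and the KEGG pathways were chosen after their values were seen, and the splits of the libraries were written down before their results were seen. HLA-B and HLA-C, class I molecules, rose over both groups by 0.82 ± 0.14 and 0.69 ± 0.14 (edgeR adjusted p = 4.7e-04 and 0.0017), or by 0.51 and 0.36 after the GC and length correction. HLA-B measured 74.2 ± 7.91 CPM in NC, 131 ± 15.8 CPM in KO21 and 132 ± 21.3 CPM in KO2 (SD, n = 3 each). HLA-E, a ligand of natural killer cell receptors, rose by 0.54. HLA-DRB1 and HLA-DRB5, class II beta chains, measured 0.0603 and 0.107 CPM in NC, 10.1 and 6.01 CPM in KO21, and 2.79 and 1.87 CPM in KO2. B2M, the light chain of class I molecules, had a log2 fold change of 0.38 and did not pass (edgeR adjusted p = 0.20), but passed after correction at 1.03 (adjusted p = 0.0077). Reads of HLA genes can be shared between paralogues.

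Of 315 KEGG pathways in the deposited annotation, camera passed 14 for both groups, 13 higher and 1 lower, and 8 of these also after the correction. Antigen processing and presentation, with 15 higher and 9 lower of 43 genes, did not pass (camera adjusted p = 0.081; adjusted p = 0.77 with an estimated correlation; 0.24 after correction). Allograft rejection had 8 higher and 1 lower of 12 genes (camera adjusted p = 1.9e-04; adjusted p = 0.77 with an estimated correlation; 0.0025 after correction). Metabolism of xenobiotics by cytochrome P450 had 8 higher and 0 lower of 19 genes (camera adjusted p = 0.0022; adjusted p = 0.77 with an estimated correlation), but did not pass after correction (0.073). Oocyte meiosis, which holds many mitotic genes, was the pathway that was lower, with 8 higher and 37 lower of 101 genes (camera adjusted p = 0.026; adjusted p = 0.77 with an estimated correlation; 0.28 after correction). In KO2 the pathway Lysosome had 36 higher and 14 lower of 108 genes (camera adjusted p = 0.014; adjusted p = 0.79 with an estimated correlation; 0.029 after correction).

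By chromosome arm, corrected medians differed between KO21 and KO2 at an adjusted p under 0.05 on 19 of 41 arms, against random draws of genes. The largest medians of KO21 less KO2 were 0.50 on 8q and 0.30 on 20q, and -0.47 on 16p, -0.42 on 8p, -0.36 on 9q, -0.35 on 6q and -0.31 on 11q. Against NC, 11 arms differed in KO21 and 15 in KO2, with 8p at -0.41 in KO21 and 8q at -0.47 in KO2. Corrected fold changes over NC of genes 20 tested genes apart on a chromosome correlated at 0.059 in KO21 and 0.070 in KO2. The highest of 1000 random gene orders was 0.032 and 0.030. Copy number differences from NC may thus contribute to the changes in each knockout group, and no DNA was measured.

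Of 100 splits of the 9 libraries into groups of 3, 1 split called as many genes as the 4843 for both groups. It was the real split, a share of 0.01. Regrouping the libraries cannot tell a knockout effect from the GC trend, since the groups are confounded with that trend. The highest other split called 3048 genes (4929 at an unadjusted p under 0.05); it left NC intact and regrouped the knockout libraries. For each comparison of 3 libraries with 3, 10 splits are too few for a share under 0.05, and 1 split, the real one, gave the count: 3499 genes for KO21, 4955 for KO2 and 2952 between KO21 and KO2. The highest other split called 0 genes with edgeR in each, with 3057, 387 and 2504 genes at an unadjusted p under 0.05.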
